A study of Mus musculus with 2 samples.

How the data were processed

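H3K4me2 ChIP-seq of mouse midbrain at embryonic day 15.5 was analysed from the deposited peak lists of 2 biological replicates, each a pool of embryos of mixed sex, and from 2 lists for the series. The authors called peaks on each replicate against its own control and on both replicates pooled, and derived the replicated list from these, per the labels and the deposited description of the lists. The exact rule behind the replicated list, the aligner, the peak caller and their versions are not given in the sources used here. Every row of the replicated list was also a row of the pooled list, and 11463 pooled peaks were left out of it. Peaks overlapping both replicates made up 90.7% of the replicated list, so it is not simply the set of such peaks.

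Each peak carries a fold enrichment over control, a ratio set by the authors' peak caller and deposited as such. It also carries the deposited -log10 of a p-value and of a q-value, which the authors' caller set. The smallest -log10 p was 2.01 in replicate 1 and 2.05 in replicate 2, so the deposited lists hold weak peaks: 90.8% and 93.2% of them had a -log10 q of 2 or more. These values are the authors' own for each peak and were used to describe, rank or filter peaks within a list. A weaker library or a higher threshold shortens and splits peaks, so covered lengths depend on the calling as well as on the mark. The lists give no read counts, so the depth per sample and the precision it sets are unknown, and intervals given here cover counting of genes only.

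Coordinates are on mouse build mm10, and annotation came from GENCODE release M21 on the same assembly, GRCm38. No peak extended past a chromosome end of that sequence. The 19 autosomes, X and Y were used, 21 chromosomes in all. Protein-coding genes were taken once per symbol, giving 21911, and a gene's start is the 5' end of the annotated gene. A start had a peak where a peak overlapped the 1 kb on either side. Covered length was counted in each replicate's own list over 10 kb on either side. Domains joined replicated peaks at most 3 kb apart and were ranked by covered bases. The ratio of observed to expected CpG was computed over 500 bases on either side of the start.

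The lists' shares of starts with a peak were compared with all other coding genes by two-sided Fisher's exact tests. Median covered lengths were compared with 100000 random lists of the same size by a two-sided permutation test, and CpG content by 100000 permutations of the genes. Benjamini-Hochberg adjustment ran over the 26 lists in each family, with a threshold of 0.05. A list could not have passed in a direction where its adjusted p stayed at 0.05 or above at the most extreme value it can take (a median of 0 bases, or a peak at no start or at every start), with the other lists' p kept. The tests treat genes as units, and neighbouring genes that share a window are not independent, so p-values describe lists in this tissue and not differences between animals. Replicate overlap needed 1 shared base. With 2 replicates of 1 group, no test between groups was made. Of 329 symbols in the 25 lists of named genes, 328 matched, and Ahsp of the erythroid list did not; the remaining list took all olfactory and vomeronasal receptor symbols.

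The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9. Overlap counts and covered lengths were checked with bedtools 2.31.1, with 0 differences over 43557 replicate 1 peaks, 46119 replicate 2 peaks and 21911 genes. Both list tests were tested on simulated data, with 25 lists of the real sizes drawn from 21911 coding genes, 5 of them changed, in 40 rounds. For the share of starts with a peak, lists simulated at 95% were recovered in 28.0% of cases and at 30% in 27.0%, with 0.25% of unchanged lists called at each. For covered length, lists lengthened 1.5-fold, 2-fold and 3-fold were recovered in 15.5%, 48.0% and 82.5%, with 0%, 0.25% and 0.125% of unchanged lists called. Smaller increases are thus often missed at these list sizes. These simulations used 2000 random lists per test, and shortened lists were not simulated.

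The lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule named the 25 coding genes with the longest mean covered length, skipping those within 10 kb of one taken, the 10 widest domains and the 5 strongest replicated peaks with their nearest coding genes, and the 2 highest and 2 lowest members of each list by covered length. It also allowed any member of the dopaminergic, patterning and GABAergic lists. Slc17a6, Pou4f1 and other members named outside it were chosen after their values were seen. The alternatives were stricter and stronger peaks, other overlap rules, the pooled list, each replicate alone, other windows, every transcript start, other random backgrounds and other merging distances. Peaks on unplaced sequences entered no gene comparison.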

Results

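Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark of promoters and enhancers that are in use or held ready for use, was profiled by ChIP-seq in the midbrain of mouse embryos at embryonic day 15.5. ChIP-seq sequences the DNA that an antibody against the mark recovers, and a peak is a region with more of it than a control. The samples formed 1 group with 2 biological replicates of strain B6NCrl and mixed sex, replicate 1 pooled from 78 embryos and replicate 2 from 62. The deposited lists held 43557 peaks in replicate 1 and 46119 in replicate 2, a mean of 44838 ± 1812 (SD, n = 2), which covered 47.2 Mb and 54.7 Mb. The authors' replicated list for the series held 36158 peaks over 54.3 Mb, 1.99% of the genome, with a median width of 1057.5 bases and a median fold enrichment of 12.4. The lists carry no read counts, so the depth of the libraries is unknown. With a single tissue and age, the comparisons were those between the replicates and those between genes, gene lists and regions within this tissue.

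The first question was which genes carried the longest H3K4me2. Covered length is the number of bases under peaks within 10 kb either side of a coding gene's start, and gene values are means ± SD of 2 replicates. Meis2, a homeodomain gene used in midbrain tectum development, had 19655 ± 489 bases and Pou3f3, a POU-domain regulator of neural development, 19620 ± 245, so that peaks filled nearly the whole 20 kb window. Their order differed between the replicates, with 19309 and 19446 bases in replicate 1 and 20001 and 19793 in replicate 2. Nr2f1 (18778 ± 941), an orphan nuclear receptor, and the POU-domain gene Pou3f2 (18539 ± 247) followed closely. Ebf3, a regulator of neuronal differentiation, had 18431 ± 387 bases, and the LIM homeodomain genes Lhx1 and Lhx5 had 17419 ± 870 and 17401 ± 861. The median over all 21911 coding genes was 2008 bases, 158 genes exceeded 10 kb, and 6139 genes (28.0%) had none.

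Further down the 25 genes ranked by covered length stood the neural stem cell factor Sox2 with 15778 ± 1220 bases, the zinc finger genes Zic4 (17319 ± 651) and Zic2 (15715 ± 523), and the Iroquois genes Irx5 (15810 ± 275) and Irx2 (15446 ± 732). Otx1, a homeobox gene of the anterior brain, had 14773 ± 875 bases, En1, which patterns the midbrain and hindbrain, had 14770 ± 1616, and Barhl2 had 14383 ± 1516. Bcl11a (14310 ± 292), Nr2f2 (13992 ± 89.1) and Zfhx4 (15672 ± 795) were also among them. Genes of other kinds stood there too, such as Setd1b, an enzyme that methylates histone H3 at lysine 4 (16555 ± 671), Asic4, a member of the acid-sensing ion channel family (15075 ± 1061), and Pcdhgc4 of the gamma-protocadherin cluster (13842 ± 1749). Skida1, Bahcc1 and Tnrc18 had 16948 ± 1043, 16804 ± 900 and 15040 ± 523 bases. The windows of 4930412O13Rik (18667 ± 566 bases) and Pcdhgc4 each held 2 other coding starts, and those of Zic4, Skida1, Setd1b, Zic2 and Bcl11a 1 each, so these lengths were not one gene's alone. All 25 had a replicated peak at the start. Covered length was greater in replicate 2 for 85.9% of the genes with any, and its rank correlation between the replicates was 0.989 across genes, which are not independent replicates.

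**Figure D1:**
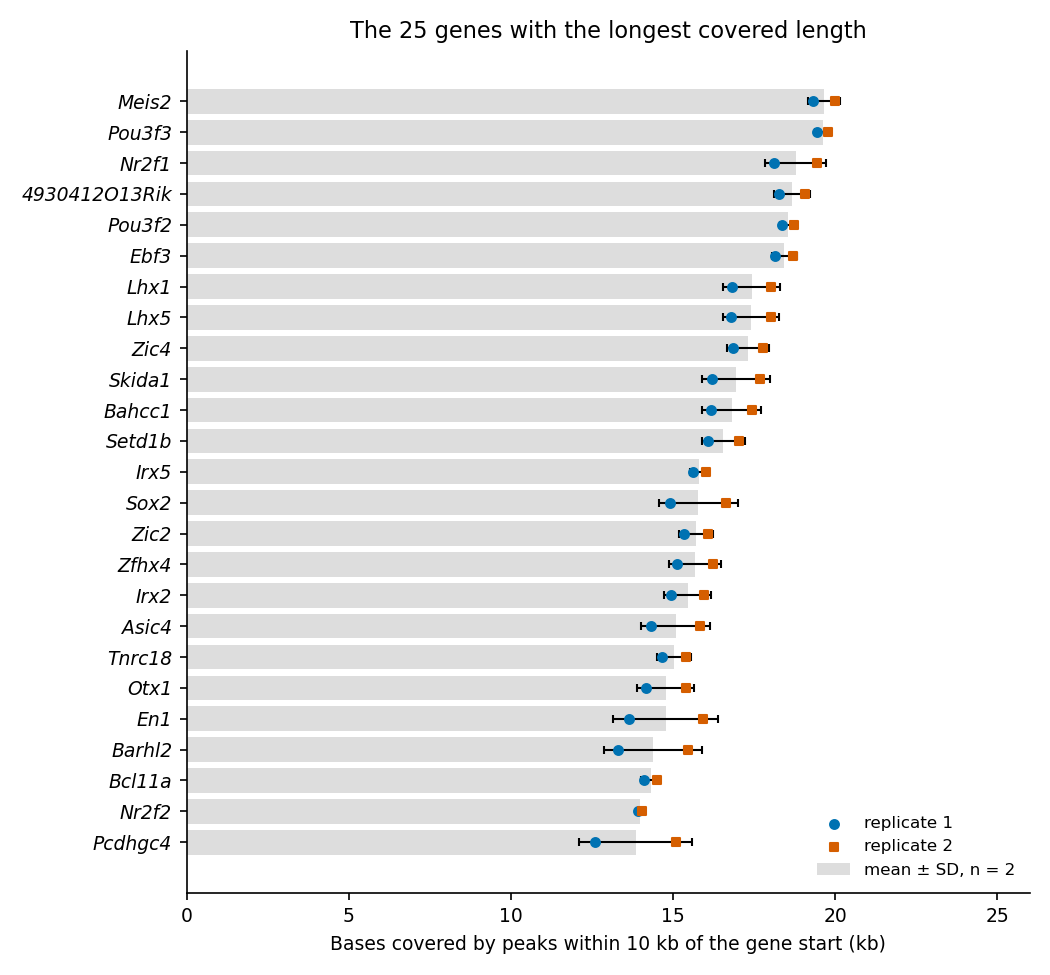
Bases covered by peaks within 10 kb of the gene start, in kb, for the 25 coding genes ranked highest by that length, leaving out genes within 10 kb of one already taken. Bars are means, error bars the SD of 2 replicates, circles replicate 1 and squares replicate 2; Meis2 and Pou3f3 reach 19655 and 19620 bases, and replicate 2 lies above replicate 1 at each gene shown.

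Joining replicated peaks at most 3 kb apart gave 27916 domains, with a median of 1440 covered bases and 173 domains above 10 kb. In that list the widest lay on chromosome 9 at positions 91350095 to 91387764 (build GRCm38), held 13 peaks with 31848 covered bases, and contained the divergent starts of Zic1 and Zic4. The second, on chromosome 13 from 83713063 to 83746258 with 31730 covered bases, contained no coding start: it held the starts of the microRNA gene Mir9-2 and the noncoding gene C130071C03Rik, and the nearest coding start, that of Mef2c, was 209029 bases away. The third, on chromosome 1 from 42682987 to 42715029, contained the starts of Pou3f3 and of the noncoding genes Pantr1 and Pantr2 and had 31587 covered bases. The fourth, on chromosome 8 from 108690957 to 108726981 with 31173 covered bases, lay inside the gene of the homeobox factor Zfhx3. It overlapped an exon but held no gene's outermost annotated start, that of Zfhx3 being 748313 bases away. Other transcript starts were not counted here, so the domain may still hold one. The next 6 contained the starts of Nr2f1, Meis2, Nr2f2, Sox2, Ebf3 and Lhx2, with 29371 to 22897 covered bases. The order of the first 4 depended on the list and the joining distance. The Mir9-2 domain had more covered bases than the Zic1 and Zic4 domain in each replicate's own list (30703 against 28074 in replicate 1 and 31976 against 30802 in replicate 2), and either list taken alone put it first. Joining within 1 kb put the Pou3f3 domain first (31587 bases), and the pooled list the one in Zfhx3 (33178 bases).

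**Figure D2:**
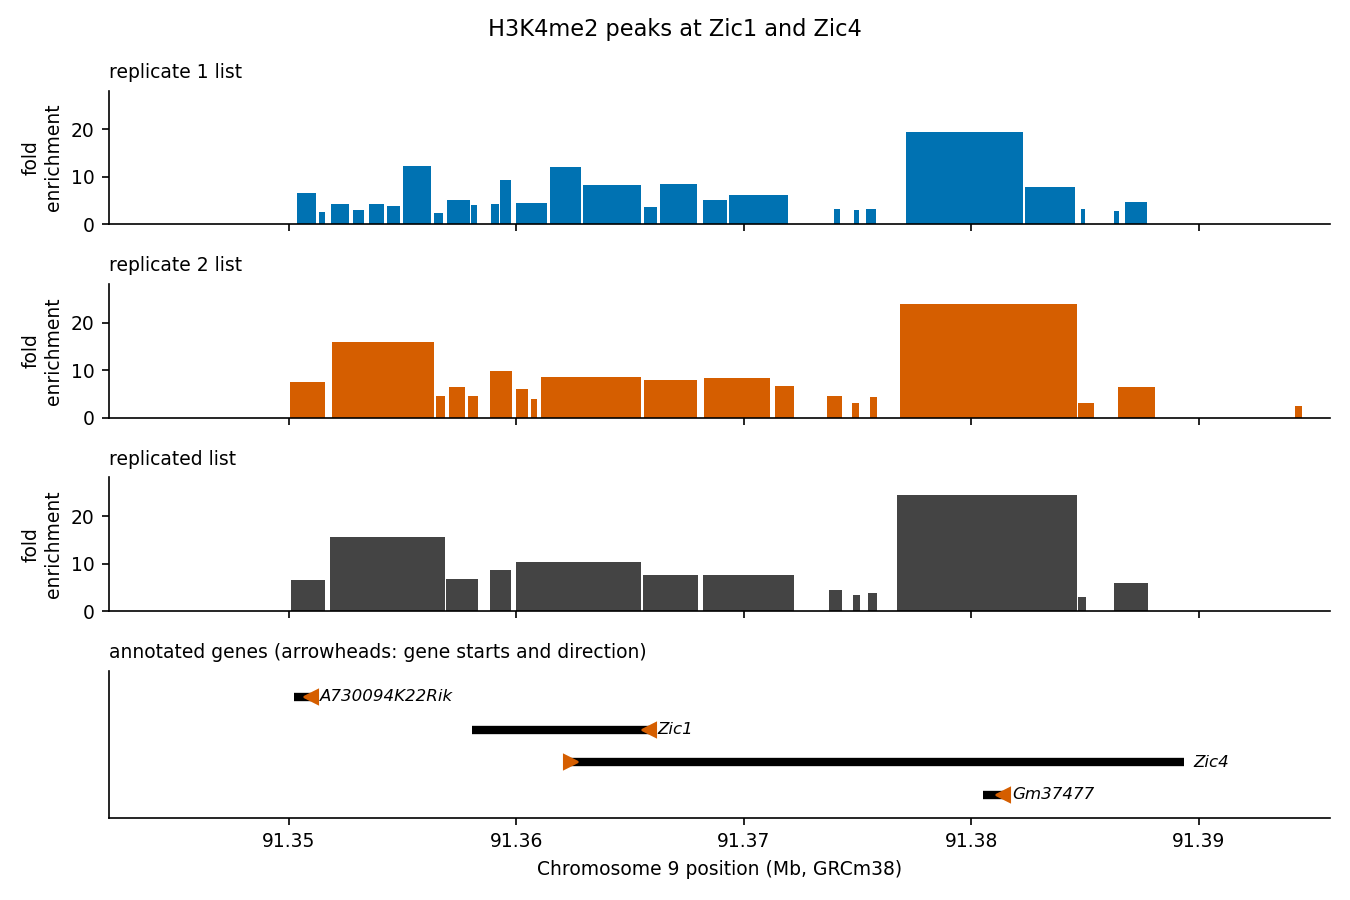
Peaks around Zic1 and Zic4 on chromosome 9 (position in Mb, GRCm38), as bars whose width is the peak and whose height is the authors' fold enrichment in the list of replicate 1, of replicate 2 and in the replicated list, above the annotated genes. The replicated list holds 13 peaks in the domain from 91350095 to 91387764, and both replicates cover most of the same span.

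The 5 peaks with the highest fold enrichment in the replicated list were far narrower and each lay over 1 coding start. They were at Bace2, an aspartyl protease (chromosome 16, 97356059 to 97358368, 70.7-fold), Col27a1, a fibrillar collagen (chromosome 4, 63213670 to 63217041, 69.9-fold), Six4, a homeobox factor (chromosome 12, 73110334 to 73113946, 69.3-fold), Tanc1, a scaffold protein of synapses (chromosome 2, 59611130 to 59614230, 69.1-fold), and Lpl, lipoprotein lipase (chromosome 8, 68879925 to 68882371, 68.4-fold). Their order differed in the replicates' own lists. Bace2 had 46.9-fold in replicate 1 and 62.7-fold in replicate 2, Col27a1 52.4 and 71.9, and Six4 57.5 and 53.7. The strongest peak in the list of replicate 2 reached 75.8-fold. None of these 5 genes was among the 25 with the longest covered length.

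Of 26 gene lists fixed before the data were examined, 10 had a longer median covered length than random coding genes and 1 a shorter one. Of the 25 lists other than the olfactory one, 24, all but Hox, could not have passed as shorter even with a median of 0, because random medians of 0 are common at their sizes, so these counts say nothing of how many lists were shorter. The midbrain glutamatergic and tectal list was widest, with a median of 10712 bases over 11 genes, against 2004 in random lists of its size (central 95% from 0 to 3371 bases). Its members Slc17a6, the vesicular glutamate transporter of these neurons, and Pou4f1 had 12126 ± 937 and 10498 ± 2961 bases, and Lmo3 was lowest at 1905 ± 434. The 13 midbrain GABAergic genes had a median of 9089 bases, among them Slc32a1, the vesicular GABA transporter (13415 ± 735), Gad2, a GABA-synthesizing enzyme (11078 ± 375), and the fate regulators Gata3 (10943 ± 1054), Gata2 (9287 ± 1016) and Tal1 (9089 ± 904). The window of Gata3 held 2 other coding starts, among them that of 4930412O13Rik. At the other end of that list stood Helt (2915 ± 1017) and Tal2 (2521 ± 496). The 15 midbrain and isthmus patterning genes had a median of 6952 bases, with En2 at 13634 ± 1529, Pax3 at 11265 ± 2710, Otx2 at 11160 ± 643 and Pax7 at 11120 ± 633, whereas the signalling genes Fgf8, Fgf17 and Wnt1 had 3994 ± 180, 2634 ± 243 and 2334 ± 372. Gbx2, expressed on the hindbrain side of the isthmus, had 5302 ± 2425 bases. Each of these 3 lists reached an adjusted p of 8.67e-05 (two-sided permutation test, Benjamini-Hochberg over 26 lists), from an unadjusted p of 2e-05, the smallest that 100000 random lists can give.

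Progenitor and neuronal lists had long H3K4me2 as well. Neural progenitor and radial glia genes had a median of 6259 bases, led by Sox2 and Sox1 (12741 ± 1019), and pan-neuronal genes one of 5573, led by Tubb3 (8050 ± 577) and Ina (7550 ± 325), both with an adjusted p of 8.67e-05 in the permutation test. Axon guidance genes (5465 bases, led by Nrp1 with 10087 ± 533) and proneural genes (5425 bases, led by Ascl1 with 10442 ± 856 and Insm1 with 8861 ± 712) had an adjusted p of 0.00013. Glutamate and GABA receptor genes (4438 bases, adjusted p = 0.00052), telencephalic transcription factor genes (4107 bases, adjusted p = 0.0013) and housekeeping genes (3798 bases, adjusted p = 0.0217) also passed the permutation test. The 10 telencephalic genes taken as restricted to the telencephalon had a median of 2984 bases, within the central 95% of lists matched on CpG content (1328 to 3540). Grin2b, an NMDA receptor subunit, had 9096 ± 653 bases, Emx2 13373 ± 979, Bcl11b 12694 ± 2.12, and Polr2a, the largest subunit of RNA polymerase II, 8735 ± 1214. The window of Polr2a held 2 other coding starts, and those of Tubb3, Ina, Fgf8, Fgf17, Pitx3 and Nfia 1 each. The calls of the receptor and housekeeping lists ended in a window of 25 kb (permutation test, adjusted p = 0.0919 and 0.108), and that of the housekeeping list also against random genes with a peak at the start (0.177) or matched on CpG content (0.0883).

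The midbrain dopaminergic list did not pass, with a median of 2743 bases (adjusted p = 0.32, permutation test). Its regulators Nr4a2 (5726 ± 11.3 bases) and Pitx3 (4380 ± 467) had more than the median gene. Lmx1b had 5440 ± 3811, from 2745 bases in replicate 1 and 8135 in replicate 2. Foxa1, Lmx1a, Foxa2, Ret, Drd2 and the transporters Slc18a2 and Slc6a3 had between 4367 and 1233 bases. No peak was listed within 10 kb of any annotated transcript start of Th, the rate-limiting enzyme of dopamine synthesis, or of Aldh1a1 in either replicate, and Ddc had 108.5 ± 153 bases around its outermost start but a replicated peak at another annotated transcript start.

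The lists that did not pass included the cell cycle genes (median 2551 bases), cranial motor and cholinergic genes (2435), meningeal and fibroblast genes (2186), oligodendrocyte lineage genes (1813), astrocyte genes (1613), endothelial and pericyte genes (1497), hindbrain monoaminergic genes (1200), muscle and heart genes (1036), germline genes (461), erythroid genes (298.5), microglia and macrophage genes (143), liver and endoderm genes (95.5) and choroid plexus genes (0). Their adjusted p ran from 0.146 to 0.785 in the permutation test, which could not have called any of these 13 lists shorter. The liver median was 191 bases in replicate 1 and 0 in replicate 2, and the germline median 269 and 653. Single members went above the median gene, such as Aurkb, a mitotic kinase (7162 ± 351 bases), Olig2, which specifies oligodendrocytes (5918 ± 1171), and Nfia (9241 ± 22.6). The 39 Hox genes, which pattern the hindbrain and spinal cord, had a median of 747 bases and an adjusted p of 0.0508, and Hoxb1 and Hoxc11 had 0. The 1462 olfactory and vomeronasal receptor genes had a median of 0 bases (adjusted p = 8.67e-05, permutation test). The Hox list passed the permutation test as shorter without replicate 2 (633 bases, adjusted p = 0.0441), against random genes with a peak at the start (1072 bases, 0.000105) and against lists matched on neighbouring starts (0.000473). Hindbrain monoaminergic genes passed against random genes with a peak at the start (1678 bases, permutation test, adjusted p = 0.0483). That setting kept only the list members with a peak at the start, which changed the medians, and not every list was run in it.

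**Figure D3:**
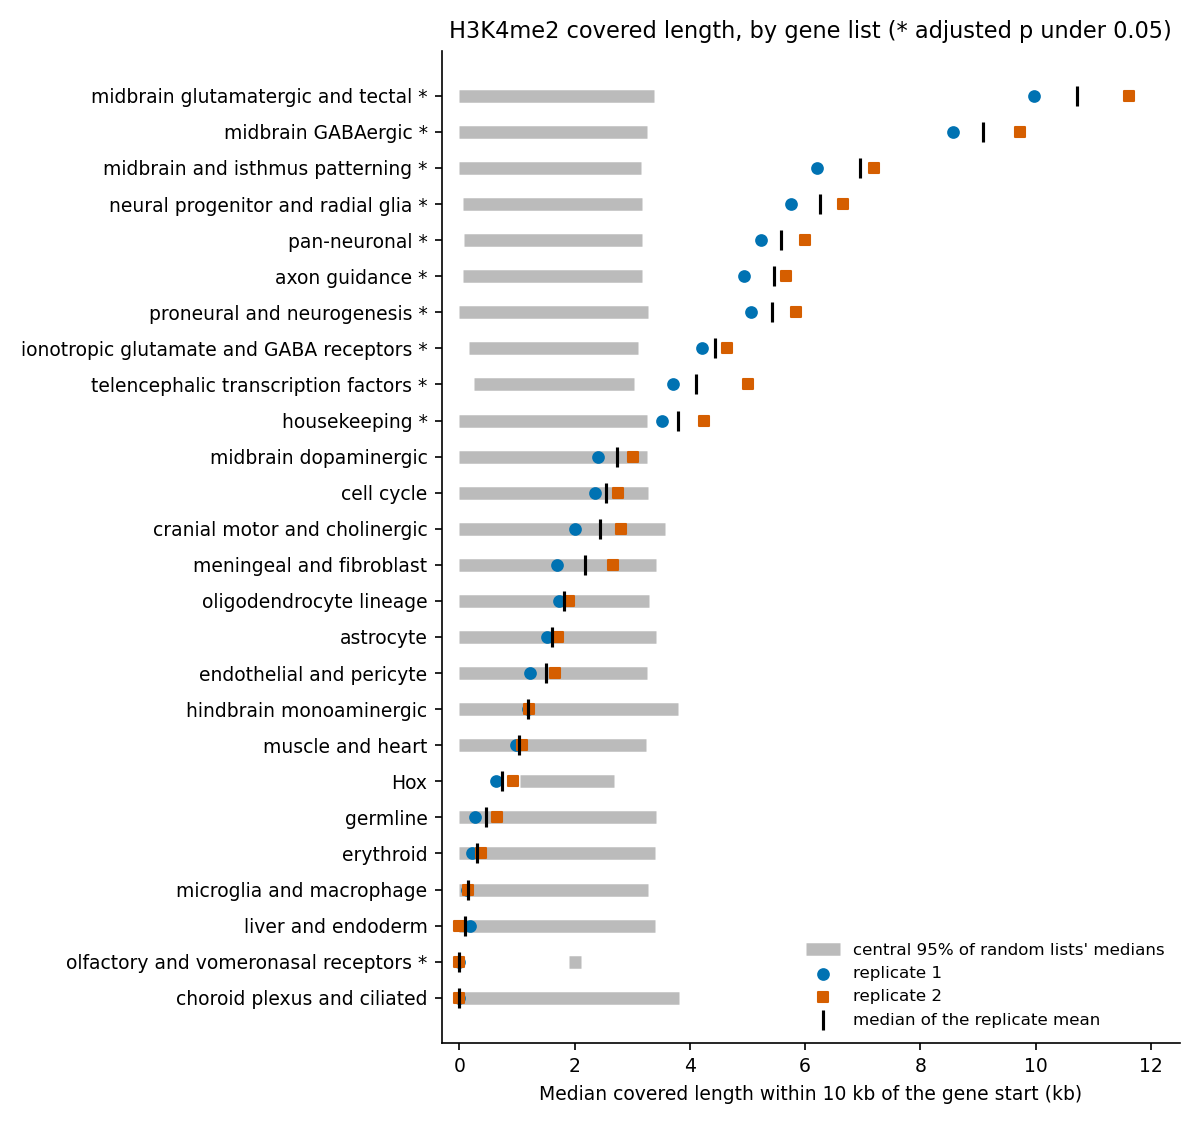
Median covered length within 10 kb of the gene start, in kb, for the 26 gene lists. Circles are replicate 1, squares replicate 2, vertical ticks the median of the replicate mean, grey bars the central 95% of medians of random lists of the same size, and asterisks mark an adjusted p under 0.05; the glutamatergic and tectal list reaches 10712 bases and the olfactory list lies at 0.

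The next question was which gene starts carried a peak at all. A replicated peak lay within 1 kb of the start of 13890 of 21911 coding genes, or 63.4% (95% exact binomial interval 62.8% to 64.0%), and of 63.6% ± 0.478 in the replicates' own lists (SD, n = 2). Of 26 lists, 8 had a higher share and 7 a lower share than all other coding genes. By Fisher's exact test, all 15 patterning genes (adjusted p = 0.00795), all 12 cell cycle and all 12 proneural genes (adjusted p = 0.0158 each) and all 11 glutamatergic and tectal genes (adjusted p = 0.0248) had one. So did 17 of 18 telencephalic transcription factor genes (adjusted p = 0.0158), and 13 of 14 genes in each of the neural progenitor, pan-neuronal and axon guidance lists (exact test, adjusted p = 0.0416 each). The tests were two-sided, with Benjamini-Hochberg adjustment over 26 lists. Among replicated peaks above the median fold enrichment only 2 of those 8 lists, the cell cycle and pan-neuronal genes, passed as higher, while the glutamatergic and telencephalic lists lay below other genes (54.5% and 55.6%). The axon guidance and telencephalic calls ended in windows of 500 bases (Fisher's exact test, adjusted p = 0.14 and 0.133), and the neural progenitor and axon guidance calls in windows of 2.5 kb (0.0724 each). Against random lists matched on CpG content, a comparison chosen after seeing the data, the proneural list passed (permutation test, adjusted p = 0.00167) and the pan-neuronal (0.12) and axon guidance (0.275) lists did not, while the other 5 could not have passed even with a peak at every start.

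Markers of microglia, blood, liver, muscle and germ cells mostly lacked a peak. By Fisher's exact test the share was lower for each of the following lists, with a peak at 1 of 12 microglia and macrophage genes (Hexb, a lysosomal enzyme; adjusted p = 0.00163), 1 of 11 liver and endoderm genes (Foxa3; adjusted p = 0.00274), 2 of 13 muscle and heart genes (Myod1 and Myf6, named after their values were seen; adjusted p = 0.00354) and 1 of 10 germline genes (Dazl, likewise; adjusted p = 0.00411). Erythroid genes had 3 of 11, at Klf1, Epor and Gypa (the last likewise; adjusted p = 0.0416), and olfactory and vomeronasal receptor genes 3 of 1462, or 0.205% against 67.9% of other coding genes, all by Fisher's exact test. The microglial genes Ptprc and Tmem119 and the embryonic globin gene Hbb-y had no covered base in either replicate. Hox genes had a peak at 17 of 39 starts (adjusted p = 0.0292, Fisher's exact test). That call was lost by Fisher's exact test without replicate 1 (48.7%, adjusted p = 0.0951), without replicate 2 (46.2%, 0.0535), in the pooled list (51.3%, 0.141) and in windows of 2.5 kb (51.3%, 0.124), whereas above the median fold enrichment the Hox share was 10.3% (adjusted p = 2.51e-09) and the erythroid call was lost (0.119). The liver share was 18.2% without either replicate and 27.3% in the pooled list or within 2.5 kb, and still passed as lower. Other shares moved as well and still passed. The microglia share was 16.7% in the pooled list or within 2.5 kb, and the germline share 20% over every transcript start or within 2.5 kb. The muscle share ran from 7.69% within 500 bases to 23.1% over every transcript start or within 2.5 kb. Of the 39 Hox genes, 36 share a window with another member. Against lists matched on CpG content, chosen after seeing the data, the Hox, germline and liver lists passed as lower, and the olfactory list was not run. The microglia (permutation test, adjusted p = 0.286) and muscle (0.12) lists did not pass. The erythroid list could not have passed as lower, and its share lay above that of matched lists (27.3% against 19.2%).

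The other 11 lists did not pass Fisher's exact test. By that exact test, dopaminergic genes had a peak at 10 of 13 starts (adjusted p = 0.469), GABAergic genes at 12 of 13 and housekeeping genes at 12 of 13 (adjusted p = 0.0612 each), and glutamate and GABA receptor genes at 14 of 16 (adjusted p = 0.0949). The counts were 7 of 8 for cranial motor, 6 of 7 for hindbrain monoaminergic, 8 of 12 for oligodendrocyte, 6 of 10 for astrocyte, 9 of 13 for endothelial, 8 of 10 for meningeal and 2 of 7 for choroid plexus genes, with adjusted p from 0.148 to 1 (Fisher's exact test). The cranial motor, hindbrain monoaminergic and choroid plexus lists were too small to pass as higher. Gad1, Notch1, Rbfox3, Ywhaz, Gabrb3, Robo1, Fezf2 and Ddc, several of them named after their values were seen, had no peak at the gene's outermost start but had one at another annotated transcript start, as did 792 coding genes in all. With every transcript start counted, the GABAergic (adjusted p = 0.0147), receptor (0.0102) and housekeeping (0.0147) lists passed Fisher's exact test with all their members, and the housekeeping list also in windows of 2.5 kb (0.0203).

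**Figure D4:**
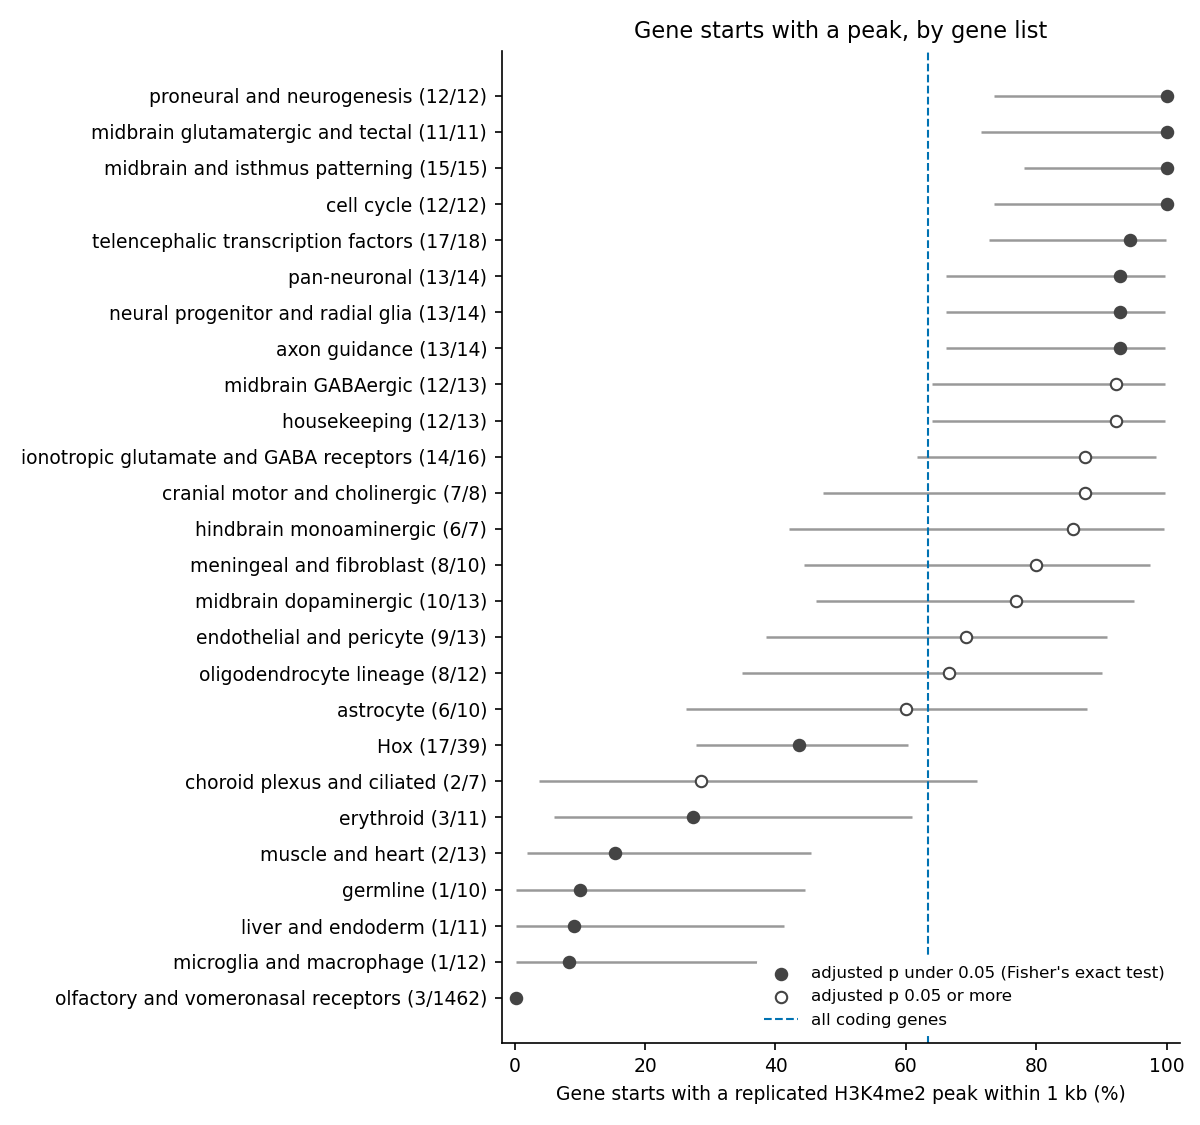
Percentage of gene starts with a replicated peak within 1 kb for the 26 gene lists, with the number of members in parentheses. Points are the observed shares, lines their 95% exact binomial intervals, filled points lists with an adjusted p under 0.05 in Fisher's exact test, and the dashed line the 63.4% of all coding genes; the lists run from 0.205% for olfactory and vomeronasal receptors to 100% for 4 lists.

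Outside coding genes, a peak lay at the start of 18.8% of 5854 long intergenic noncoding genes, 38.3% of 2959 antisense genes and 2.69% of 9940 processed pseudogenes. Counting only starts away from coding starts, the shares were 13.0%, 11.8% and 2.00%. Coding starts with a peak were richer in CpG dinucleotides: the median ratio of observed to expected CpG was 0.720 with a peak and 0.171 without, a difference of 0.549 (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations give).

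Of the replicated peaks on the assembled chromosomes, 45.1% lay within 1 kb of a coding or noncoding gene start, 34.4% elsewhere in genes and 20.5% between genes, whereas those parts make up 3.75%, 42.5% and 53.7% of the genome. A peak counted at a start if it overlapped that window at all, while the genome shares count bases. The 2 kinds of share are thus not measured alike, and wide peaks placed at random would exceed 3.75%. The peaks at gene starts had a median width of 1983 bases against 664 for the others and a median fold enrichment of 27.2 against 5.17, and they held 67.2% of the bases covered. In the replicates' own lists 40.1% ± 2.79 of peaks lay at gene starts (SD, n = 2). The share at gene starts rested on peak strength, at 76.4% among peaks above the median fold enrichment.

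The replicates were compared by overlap and by rank. Of replicate 1 peaks, 89.8% overlapped a replicate 2 peak by at least 1 base, and of replicate 2 peaks 74.5% overlapped one of replicate 1, a mean of 82.1%, while shuffled replicate 1 peaks overlapped at 3.75% ± 0.0955 (SD over 100 shuffles). Peaks without a partner were weaker and narrower: their median fold enrichment was 2.97 against 9.25 in replicate 1 and 3.22 against 15.3 in replicate 2, and their median width 217 against 812 bases and 262 against 1090. Across the 32849 regions with a peak in both, Spearman's rho of fold enrichment was 0.925 and Pearson's r of its log2 was 0.944, over regions that are not independent replicates. Of the replicated peaks, 90.7% overlapped a peak in each replicate's list, 604 only in replicate 1, 2647 only in replicate 2, and 119 in neither.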

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

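The tests of forebrain tissue and of a longer peak list below were chosen after the results they measure were seen, and the other tests of this part before. In the replicated list, 16 peaks lay on unplaced or unlocalised sequences that entered no gene comparison, above the 3 that a count of 0 allows, with fold enrichments from 2.72 to 15.5.

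Telencephalic transcription factor genes carried long H3K4me2 in midbrain, with a median of 4107 covered bases. High CpG content within 500 bases of the start, which the matching covered, is argued against as the whole cause. The list lay at the 99.9th percentile of 10000 random lists matched on that content, whose medians centred on 2434 bases (central 95% from 1838 to 3384). CpG-rich sequence further out in the 20 kb window was not matched and stays open. The 10 members taken as restricted to the telencephalon, such as Foxg1, Emx1 and Tbr1, had a median of 2984 bases, at the 90.5th percentile of matched lists (central 95% from 1328 to 3540), a level that forebrain tissue in the samples could give. Ordinary genes of the same CpG content reach it too, so this value does not separate forebrain tissue from starts that carry the mark in any tissue. The other 8 members, which belong to the same telencephalic list, had a median of 9574 bases. The split was made by gene name and not from expression in these samples, so their longer length does not argue against forebrain tissue. Of the 18 members, 4 share part of a window with another. No biological explanation was tested, as the design has a single tissue.

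Replicate 2 peaks covered more bases than replicate 1 peaks, by a factor of 1.16 in all and 1.11 over the 32849 regions shared, with more bases in 78.9% of them. The extra peaks in the longer list of replicate 2 are argued against as the whole cause, because the 30000 strongest peaks of each list, shared or not, gave a factor of 1.145 (1.12 to 1.16 over 20 chromosomes). Higher enrichment over control in replicate 2 stays open: the median ratio of fold enrichment was 1.32, but across shared regions the log2 ratios of covered bases and of fold enrichment had a Spearman's rho of 0.0651 (-0.0094 to 0.128 over chromosomes), between the bounds set beforehand. A higher read depth was not tested, as the lists give none, and no biological explanation was tested for replicates of one group.

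Fewer X-linked than autosomal coding starts carried a peak, 463 of 948 (48.8%, 95% exact binomial interval 45.6% to 52.1%) against 13423 of 20780 (64.6%, 63.9% to 65.2%; Fisher's exact test, p = 4.66e-22), while single autosomes ran from 52.2% (chromosome 7) to 77.1% (chromosome 12). Fewer CpG-rich starts on X do not account for all of it: autosomal lists matched on CpG content had 55.1% (central 95% from 53.2% to 57.1%), nearer to X than all autosomal starts, but the X share lay at percentile 0 of 10000 of them. Near-identical gene copies are a candidate explanation that the test cannot single out. Symbol families were genes on one chromosome with the same symbol up to its first digit, and their sequences were not compared. Without families of 5 or more, which took out 398 X-linked genes, the X share was 69.1% against 78.9% on autosomes. Autosomal lists also matched on CpG content had 70.2% (67.8% to 72.5%), with X at the 18.1th percentile. Leaving out unrelated genes with a shared symbol stem, or families silent in brain, could give the same value. Enrichment at X-linked starts with a peak was 0.609 times the autosomal level (median 18.5 against 30.3, with single autosomes from 29.1 to 31.7), which may also cost starts near the threshold. The sex of the embryos, mixed in both pools, was not tested.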

How the results depend on the processing

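The random lists matched on CpG content were chosen after seeing the data, the other alternatives before. Covered length was not run on the pooled list, on peaks above the median fold enrichment or over every transcript start, and CpG content not in other windows. Under the alternatives set before and run for each, CpG content and the 10 lists with a longer covered length kept their direction. So did the 7 lists with a lower share, and the counts of these lists stayed within 1.5 times. Matched on CpG content, the 10 longer lists kept their direction too, but only 3 lists passed as lower in share, with the olfactory list not run. The erythroid share then lay above that of matched lists (27.3% against 19.2%). The microglia and muscle shares stayed below matched lists without passing. The receptor and housekeeping lists lost their longer call in some settings. Hox lost its lower share in the pooled list, within 2.5 kb and without either replicate, and the erythroid list lost its own above the median fold enrichment. Restricting to peaks above the median fold enrichment gave a replicate overlap of 93.7%, a rank correlation of 0.791, 59.5% of coding starts with a peak, 76.4% of peaks near a start and 2 lists with a higher share, and put the glutamatergic and tectal (54.5%) and telencephalic (55.6%) lists below other genes, with an adjusted p of 0.918 each in Fisher's exact test. Reciprocal 50% overlap gave 64.7%, and a -log10 q of 2 or more a rank correlation of 0.921. Coding starts with a peak came to 64.1% in the pooled list, 67.0% over every transcript start, 62.4% within 500 bases and 65.3% within 2.5 kb, and peaks near a start to 36.4%, 53.2% and, within 2.5 kb, 51.9%. Leaving out a replicate gave 63.2% to 63.9% of starts, 38.1% to 42.1% of peaks near a start, and 1 to 2 lists with a shorter covered length, the second being Hox without replicate 2. Lists with a shorter length numbered 3 against random starts with a peak and 2 when matched on neighbouring starts. The first of these settings kept only list members with a peak at the start, and not every list was run in it. Matched on CpG content, 2 were shorter, 2 had a higher share and 3 a lower share, with the olfactory list left out, but of the 25 lists 7 could not have been called shorter, 9 higher or 1 lower in share. Merging over the larger distance raised the widest domain to 40722 bases, at a place on chromosome 13 outside the 10 domains, and kept 6 of the 10. Apart from fewer or more peaks entering, the cause was not tested. Of the 25 widest genes, 7 moved by more than 1 SD in the replicated list and 2 at the stricter q. No paired analysis was possible because there was a single group, and leaving out a replicate leaves no pair to overlap or correlate. Unknown depth limits what a missing peak shows: it was not detectable in these lists, not absent.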

Other observations

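All tests and groupings in this part were chosen after the results were seen. Hox and germline genes had less of the mark than random lists matched on CpG content. Hox genes had a median of 747 covered bases against 2576 in matched lists (adjusted p = 0.000625, permutation test with 10000 lists, over 25 lists) and a peak at 43.6% of starts against 89.4% (adjusted p = 0.00167). Germline genes had 461 bases (269 in replicate 1 and 653 in replicate 2) against 2080 (adjusted p = 0.008) and a peak at 10% of starts against 69.3% (adjusted p = 0.00167, permutation test). Of 10062 coding starts with an observed to expected CpG ratio of at least 0.6, 98.4% had a peak and 164 had none. Only 12 of 25 such Hox starts had one and 1 of 5 such germline starts: Dazl had one, while Ddx4, an RNA helicase of germ cells, the synaptonemal complex genes Sycp1 and Sycp3, and Mael had none. Both lists were taken because they were already low against matched lists in the same peaks, so no test of these counts is given. Of the 39 Hox genes, 36 also share a window with another member. Liver and endoderm genes had a peak at 9.09% of starts against 43.1% in matched lists (adjusted p = 0.011, permutation test). The matched test was run on the replicated list only. In each replicate's own list the liver share was 18.2%, and in the pooled list 27.3%.

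At the other extreme, 8.71% of 7259 coding starts with a CpG ratio under 0.3 had a peak. Neuronal genes were among them. The CpG ratio was taken over a shorter stretch around the gene's outermost start than the peak call and the covered length. A low ratio beside a peak or long coverage, as in the genes below, thus does not show that the peaks lay on CpG-poor sequence. Lists matched on CpG content used the same ratio, so sequence further from the outermost start was not matched. Nhlh1, a helix-loop-helix factor of new neurons, had a CpG ratio of 0.07 and 5102 ± 1498 covered bases (SD, n = 2), the guidance receptor gene Plxna2 a ratio of 0.113 and 7373 ± 32.5 bases, and Stmn2, a microtubule regulator of growing axons, a ratio of 0.255 and 6570 ± 153 bases. As groups, proneural genes had a peak at 100% of starts against 66.6% in lists matched on CpG content (adjusted p = 0.00167, permutation test), and glutamate and GABA receptor genes at 87.5% against 65.0% (adjusted p = 0.005). Of the other lists with a higher share in the report, the pan-neuronal and axon guidance lists did not pass this matched test, and 5 could not have passed it even at 100%. For covered length, 9 lists remained longer than CpG-matched lists, all of them among the 10 of the report; the housekeeping list did not (adjusted p = 0.0883, permutation test).

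Some genes had many peaks far from coding starts around them. Of the replicated peaks, 14631 (40.5%) had their midpoint over 5 kb from every coding transcript start. Zfhx3, a homeobox factor, was the nearest coding gene of 41 of them, Adgrl2, an adhesion receptor, of 32, Tenm3 and Zfp608 of 28 each, Sox2 and the predicted gene Gm11146 of 26 each and Nr2f2 of 25, whereas the median among the 5986 genes with any was 1. Part of this is the room around a gene. Per 100 kb of sequence nearest to it, Gm11146 had 4.27 such peaks, Sox2 3.11, Zfhx3 3.06, Adgrl2 1.37 and Tenm3 0.942, against 0.537 over the genome. The nearest gene is not shown to be the gene that such a region acts on.

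Several gene families had more than one member with long H3K4me2. Their median covered lengths were 15320 bases for the 5 Zic genes, 13992 for the 3 Nr2f genes, 13772 for the 4 Pou3f genes, 10641 for the 6 Irx genes and 10470 for the 4 Ebf genes. Random lists of the same size and CpG content centred on 2425, 2772, 2769, 2952 and 2802 bases. The windows of Zic1 and Zic4 overlap, as do those of Zic2 and Zic5, so the same peaks count for more than 1 of the Zic genes. These families were picked because a member stood among the 25 longest genes, so no test of them is given.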
